A study of Mus musculus with 2 samples.

How the data were processed

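Small RNA was sequenced from the forebrains of 2 newborn mice, and the labels place both in 1 group. The labels name separate pups, pup 1 and pup 3, and list the same donor record for both. Litter, batch and sex were not given in the sources used here.

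The deposited values are counts of reads per microRNA gene, made by the authors on assembly mm10 with annotation release M4, per the file headers and the notes beside each table. The aligner, the counting tool, their versions and their settings are not given in the sources used here. Each table holds 3 columns of whole-number counts without a heading. In all 1973 genes the first column equals the sum of the other columns, which were read as holding reads on the sense and on the opposite strand of the gene. The first column was used because the notes name none. The tables also hold 4 tallies that name no gene, and these stayed out of library sizes and tests. In pup 1, 43.0% of all reads were tallied as mapping to several places, 14.9% as unmapped and 1.85% as in no gene. In pup 3 the shares were 43.5%, 14.4% and 1.26%. No read was tallied as ambiguous, which allows a share of up to 1.71e-05% in pup 1 and 2.04e-05% in pup 3 by the upper 95% Wilson limit. Since a gene's count holds reads of both arms, arms cannot be compared, and since reads that map to several places are not in the counts, hairpins with near-identical copies can be undercounted.

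Gene names, positions and host genes came from GENCODE M21 on GRCm38, the assembly that mm10 names, by gene identifier. Of the 1973 identifiers, 1894 matched, and the other 79 held 5 reads in pup 1 and 4 in pup 3. A hairpin was marked as shared when it had a stretch of at least 20 nucleotides, on either strand, in common with an annotated hairpin at another place. This search covered 1894 hairpins and not the genome. By this rule 929 were shared, of which 94 were detected. GC content was computed from the hairpin and not from the mature microRNA.

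CPM is a gene's count per 1000000 reads assigned to genes. A gene counted as detected with 10 or more counts in both pups. The ratio of pup 3 over pup 1 was computed on counts with 0.5 added, scaled by edgeR's TMM factors (1.07 for pup 1 and 0.933 for pup 3). The spread between pups was estimated with estimateDisp of edgeR 4.0.16 in an intercept-only design, over genes with 10 CPM or more in both. Genes with a total of 20 or more counts were tested with a two-sided exact conditional binomial test and Benjamini-Hochberg adjustment at 0.05. There was no edgeR test of a contrast, since 1 group has none.

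The 18 microRNA lists, the 35 genomic clusters, the main tests of the report and their settings were fixed before the data were examined. The search for shared stretches, and the tests and settings said to be added or chosen after the data were seen, were not. A list's median CPM was placed among 10000 random lists of the same size in each pup. A list's median log2 ratio was placed among 10000 random lists matched on mean expression in 10 bins, for 13 lists with at least 3 members at a mean of 10 CPM or more. Values outside percentiles 2.5 to 97.5 were counted as apart. The text names by rule the 20 genes with the highest mean CPM, the 5 highest and 5 lowest log2 ratios among genes with a mean of 50 CPM or more, and the 2 most abundant members of each list. Other genes named were chosen after their values were seen.

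The alternatives were size factors of DESeq2 1.42.0, total counts, the other strand columns, other count minimums, random lists drawn from detected genes, and each pup alone. Leaving out members with shared stretches and removing a linear trend on hairpin GC content were added after the data were seen. Permutation tests used 100000 permutations. The work ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

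The tests were checked on simulated counts for this comparison. The exact binomial test on 455 genes recovered 52%, 66%, 78% and 94% of 50 genes each changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, and called 2.30% of 261 unchanged genes. The simulated counts for this test held counting error only and no spread between pups. The 2.30% is therefore not a rate of false calls between real pups. Matched random lists, on 314 genes, found 18 of 20 lists lowered by 0.5 on the log2 scale and 0 of 20 unchanged lists. Each of these lists held 20 genes drawn at random, simulated independently with a biological coefficient of variation of 0.25. The check therefore does not cover lists of other sizes or lists of neighbouring hairpins. A biological coefficient of variation of 0.25 was recovered as 0.240 over 306 genes.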

Results

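MicroRNAs were measured by sequencing of small RNA from the forebrain of newborn mice (postnatal day 0, strain B6NCrl). The samples form 1 group of 2 biological replicates, each a whole forebrain of a separate pup. Replicate 1 came from pup 1 and replicate 2 from pup 3, and the sex of the pups was not recorded. With a single tissue and age, the design implies a description of the newborn forebrain and of the spread between its pups, and no comparison between conditions. The library of pup 1 held 22470992 reads, of which 9037087 were assigned to a microRNA gene (40.2%, 95% Wilson interval 40.20 to 40.24). The library of pup 3 held 18798326 reads, of which 7678662 were assigned (40.8%, 40.83 to 40.87). Each value below is a count per hairpin gene, so both arms of a hairpin are pooled.

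A small number of hairpins supplied most of the reads that were assigned to a microRNA gene, which leave out reads mapping to several places. Mir99a, a member of a family known to repress Mtor, alone took 20.9% ± 0.802 of the assigned reads (SD, n = 2). The let-7 hairpins Mirlet7g and Mirlet7i, whose products restrain progenitor growth and oppose Lin28, followed with 7.21% ± 0.15 and 5.32% ± 1.27. Mir126a, a microRNA of endothelial cells, held 3.87% ± 0.256, and Mir137, a brain-enriched regulator of neuronal maturation, held 2.90% ± 0.654. The 10 most abundant genes together took 52.6% of the assigned reads in pup 1 and 53.5% in pup 3.

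Of the 1973 genes in the tables, 433 had 10 or more counts in both pups and 1198 had no count in either. A mean of 1000 counts per 1000000 assigned reads (CPM) or more was reached by 102 genes, and a mean of 10000 CPM or more by 17. Mir99a (ENSMUSG00000065530.1) lies on the plus strand of chromosome 16 from 77598936 to 77599000 (GRCm38), in an intron of the noncoding host gene Mir99ahg. Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9 from 106178840 to 106178927, in an intron of Wdr82, and Mirlet7i (ENSMUSG00000065406.2) lies in no annotated host gene, on chromosome 10 from 122985640 to 122985724. Mir126a (ENSMUSG00000065540.1) overlaps an exon of the endothelial gene Egfl7 on chromosome 2 from 26591357 to 26591429. Mir137 (ENSMUSG00000065569.1) overlaps an exon of the noncoding gene Gm26871 on chromosome 3 from 118433857 to 118433929.

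The rest of the 20 most abundant genes came from several known families. Mir487b of the imprinted Dlk1-Dio3 region held 2.99% ± 1.11, and Mir335, in an intron of the imprinted gene Mest, held 2.92% ± 0.278. Mir487b shares a stretch of 20 or more nucleotides with another hairpin, so its count is uncertain. The Mir99a relatives Mir100 and Mir99b held 2.51% ± 0.252 and 1.26% ± 0.167, and the let-7 genes Mirlet7b and Mirlet7d held 1.38% ± 0.172 and 0.927% ± 0.0503. Mir17, of a polycistron that promotes progenitor proliferation, held 1.28% ± 0.557. Mir130a held 2.46% ± 0.280, Mir30e 1.95% ± 0.807, Mir149 1.40% ± 0.106 and Mir26b 1.26% ± 0.0571. Mir135b held 1.21% ± 0.311, Mir181c 1.21% ± 0.00265, Mir22 0.961% ± 0.0922 and Mir15a 0.941% ± 0.398 (each SD, n = 2).

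**Figure D1:**
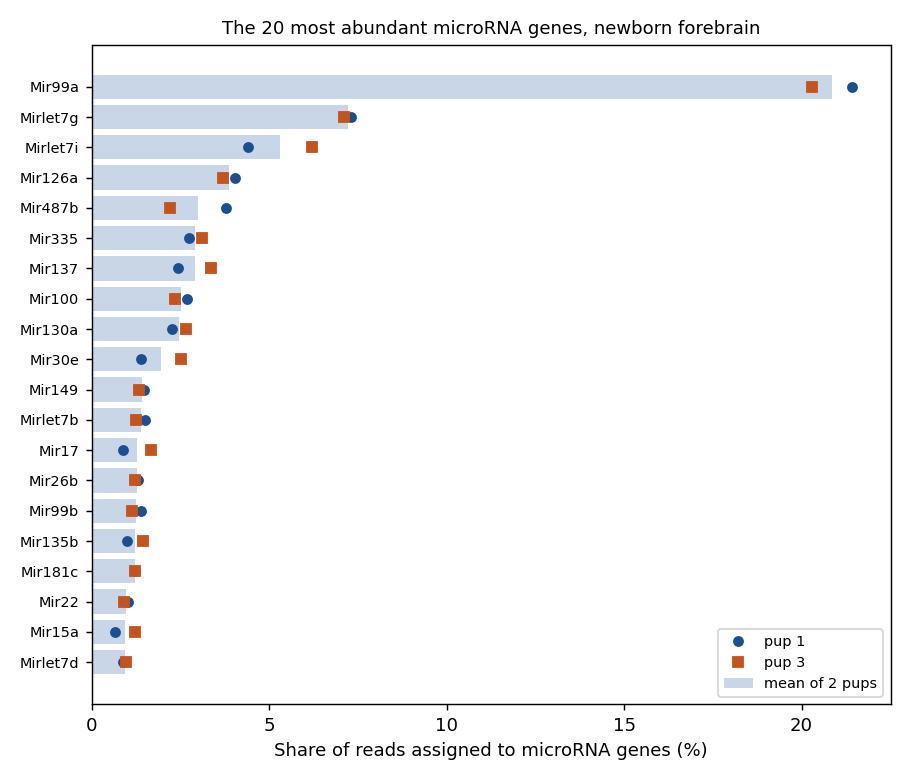
Share of the reads assigned to microRNA genes (%, horizontal axis) of the 20 most abundant genes, with bars at the mean of the 2 pups and symbols for each pup. Mir99a lies at 20.9%, apart from Mirlet7g at 7.21% and all genes after it.

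On the mean of the pups, the let-7 and related families, the imprinted 12qF1 region, neuronal microRNAs and an endothelial microRNA took the largest shares of assigned reads among the 18 lists. In pup 3 alone, the miR-17-92 list with 4.12% was above endothelial Mir126a with 3.69%. The let-7, miR-125 and miR-99/100 families together took 42.4% ± 0.153 of the assigned reads over 16 measured genes (SD, n = 2). Of these genes, 7 share a stretch with another hairpin and can be undercounted. The share also leaves out reads counted at Gm25927 (5467 CPM) and Gm24111 (165 CPM), which lay on the strands of Mirlet7e and Mirlet7f-1. The imprinted Dlk1-Dio3 region at 12qF1, a large microRNA cluster of placental mammals, took 8.82% ± 2.98 over 52 measured genes. This leaves out reads counted at Gm25252 (6089 CPM), Gm24321 (3051 CPM) and Gm25750 (1136 CPM), which lay on the strands of the 12qF1 hairpins Mir376a, Mir409 and Mir380. Neuronal microRNAs took 5.47% ± 0.654 over 23 genes, led by Mir137 and by Mir128-1, a brain-enriched microRNA at 5919 ± 1152 CPM. Of these 23 genes, 15 share a stretch with another hairpin and can be undercounted, Mir128-1 among them. Endothelial Mir126a took 3.87% ± 0.256, and the proliferation-linked miR-17-92 cluster with its paralogs took 3.49% ± 0.896 over 15 genes.

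The other lists took smaller shares. MicroRNAs of choroid plexus and multiciliated cells took 1.246% ± 0.204, led by Mir449a of multiciliated cells (5509 ± 1134 CPM) and Mir204 of choroid plexus (4538 ± 1010 CPM). Epithelial microRNAs took 0.868% ± 0.472, led by Mir429 and, on the mean of the pups, Mir200b, although Mir203 was above Mir200b in pup 1. Mural and mesenchymal microRNAs took 0.566% ± 0.0445, led by Mir143 of smooth muscle (5317 ± 446 CPM). The sensory miR-183 cluster took 0.166% ± 0.120. The miR-29 family, which accumulates as the brain matures, took 0.0871% ± 0.0113, and oligodendrocyte microRNAs took 0.0664% ± 0.00166, led by Mir338 (548 ± 45.0 CPM). Leukocyte and microglial microRNAs took 0.0759% ± 0.00707, and erythroid microRNAs, led by Mir451a (271 ± 112 CPM), took 0.0310% ± 0.00984. Those of liver, gut and pancreas took 0.0594% ± 0.00361. Hox cluster microRNAs, which mark tissue behind the forebrain, took 0.0172% ± 0.00334 and were led by Mir10b (95.2 ± 1.32 CPM). Muscle microRNAs took 0.0135% ± 0.00625, where 5 of 9 measured hairpins share a stretch with another and can be undercounted. The share was 0.0112% ± 0.00256 for pluripotency microRNAs and 0.000386% ± 6.13e-05 for the X-linked testis cluster (each SD, n = 2).

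In the miR-29 family, Mir29a stood at 496 ± 77.3 CPM and Mir29c at 365.4 ± 35.2 CPM (each SD, n = 2). Mir219a-1 of the oligodendrocyte list stood at 91.8 ± 18.4 CPM and Mir145a of the mural and mesenchymal list at 183.6 ± 14.5 CPM. Of the leukocyte and microglial list, Mir142b stood at 294 ± 64.3 CPM, with reads on the strand opposite to it, and Mir150 at 213.8 ± 7.99 CPM. Mir144 of the erythroid list stood at 28.0 ± 11.7 CPM. Mir182 and Mir183 of the sensory list stood at 869 ± 745 and 477 ± 210 CPM. Of the liver, gut and pancreas list, Mir375 stood at 279.8 ± 48.9 CPM and Mir192 at 102 ± 17.5 CPM, and Mir10a of the Hox clusters stood at 65.7 ± 25.7 CPM. Mir206 of the muscle list stood at 69.7 ± 35.6 CPM and Mir208b of the same list, in an intron of the myosin gene Myh7, at 47.9 ± 22.6 CPM. The pluripotency hairpins Mir302a and Mir302d stood at 40.4 ± 5.59 and 35.2 ± 4.84 CPM, and the testis hairpins Mir741 and Mir881 at 3.01 ± 0.346 and 0.251 ± 0.198 CPM. Of these, Mir29c, Mir219a-1 and Mir302a share a stretch with another hairpin, so their counts are uncertain.

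The median CPM of 12 of the 18 lists lay in the top 2.5% of random lists of the same size in each pup. These included the muscle list and the list of liver, gut and pancreas, whose shares were small, since most genes in the tables had few or no counts. Over members without a shared stretch, a setting added after the data were seen, 9 lists did, and the leukocyte, mural and muscle lists did not. Against random lists drawn only from detected genes, 3 lists stayed there, namely the neuronal list, the let-7, miR-125 and miR-99/100 list and the endothelial list of 1 measured gene. These percentiles describe the libraries, since genes are not replicates.

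Some hairpins of microRNAs known to be prominent in neural tissue had few counts, while other shared hairpins had many. These genes were chosen after their values were seen. The neuronal hairpins Mir124a-1, Mir124a-2 and Mir124a-3 stood at 9.85 ± 6.88, 1.497 ± 1.01 and 2.41 ± 0.277 CPM, and Mir9-2 stood at 1.45 ± 0.166 CPM, while Mir9-3 stood at 533 ± 213.8 CPM and Mir181a-1 at 7826 ± 457 CPM (SD, n = 2). All of these share a stretch of at least 20 nucleotides with another hairpin. In the same libraries 43.0% and 43.5% of all reads were tallied as mapping to several places and were assigned to no gene. In 13 of 15 genomic clusters that hold both kinds, the hairpins with a shared stretch had a lower median CPM than their partners without one (exact two-sided sign test p = 0.00739). The values of multi-copy hairpins are therefore uncertain. The Mir124a and Mir9 hairpins lie in none of these clusters, so the sign test does not cover them, and the clusters are not all independent. Counts of the table column used here also do not separate strands, and 2.69% of assigned reads in pup 1 and 1.91% in pup 3 lay opposite to the named gene.

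**Figure D2:**
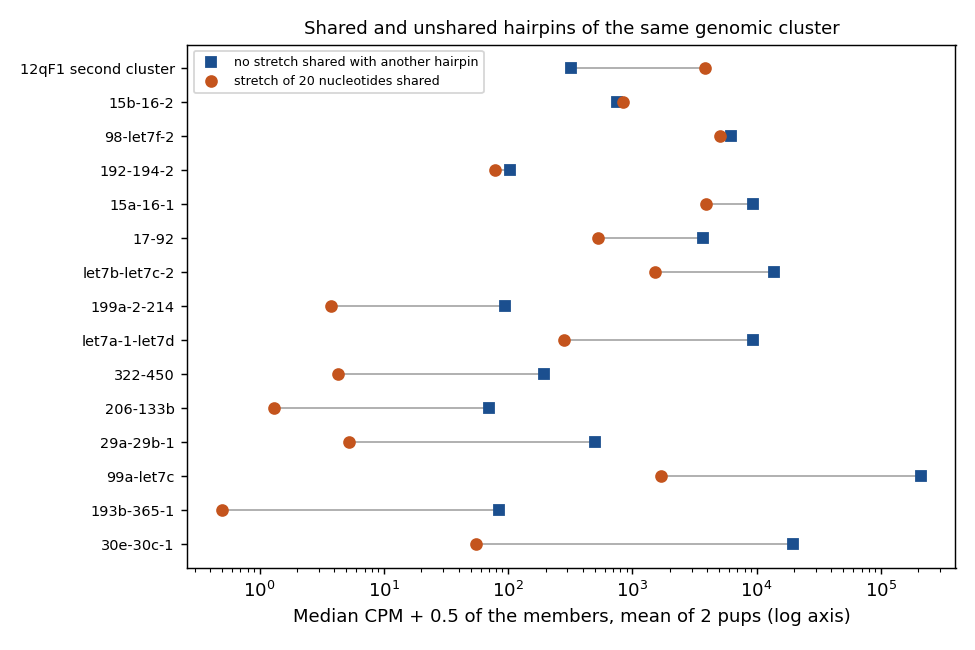
Median CPM plus 0.5 (mean of the 2 pups, log axis) of hairpins with a stretch of 20 nucleotides shared with another hairpin (circles) and without one (squares) in 15 genomic clusters. The shared hairpins lie lower in 13 clusters and higher in the cluster of Mir15b and Mir16-2 and in the second 12qF1 cluster.

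Epithelial and sensory microRNAs were higher in pup 3 and imprinted 12qF1 microRNAs were lower, beyond random lists of matched expression. Most members of each list lie in a few genomic clusters, while the random lists ignored position, so this describes these libraries only. The miR-17-92 list was also higher, but not beyond such lists among members with a mean of 100 CPM or more. Mir182 of the sensory miR-183 cluster was 4.69-fold higher in pup 3, and the epithelial Mir200a and Mir200b were 4.52-fold and 4.26-fold higher. Mir496a of the imprinted region was lower in pup 3, at 0.393 of its level in pup 1. The most abundant gene, Mir99a, differed little, with a log2 ratio of pup 3 over pup 1 of 0.12 that turned to -0.08 when the libraries were scaled by total counts. All ratios are between single libraries, so tests on them compare these libraries and not conditions.

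The spread between pups was far larger than counting error. A chi-square test of homogeneity gave 393450 on 525 degrees of freedom. This sets the libraries against counting error alone and cannot show that they are separate animals, and they were counted as 2 samples because the labels name separate pups. The biological coefficient of variation from edgeR was 0.304 over 301 genes. Across 310 genes with a mean of 10 CPM or more, Pearson's r of log2 CPM was 0.978 and Spearman's rho was 0.976, where genes are not independent replicates. Exact binomial tests with Benjamini-Hochberg adjustment called 290 of 460 genes, 139 higher and 151 lower in pup 3. Scaled by total counts, 98 of 304 called genes were higher and the others lower, as that scaling moved the median log2 ratio of the 310 genes by -0.20. Of the 310 genes, 24 were at least 2-fold higher and 12 at least 2-fold lower in pup 3. Intervals and tests on counts cover counting error only, since each pup is a single library. No molecular identifiers are named for these libraries, so repeated reads of the same molecule could make these intervals too narrow even for that.

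Imprinted 12qF1 microRNAs were lower in pup 3 as a group. Of 44 members with a mean of 10 CPM or more, 35 were called lower, 5 were called higher and 4 did not pass the exact binomial test; adjusted over the list alone, 36 were lower and 5 higher. The median log2 ratio was -0.43, a fold of 0.741, at percentile 0 of 10000 random lists matched on expression. The members lie in 1 region, while the random lists were drawn without regard to position. Since neighbouring hairpins need not vary independently, this percentile describes the list in these libraries only. Mir487b had a log2 ratio of -0.58 (95% exact binomial interval -0.59 to -0.57) and Mir411 of -0.08 (-0.09 to -0.06), while Mir496a had -1.35 (-1.41 to -1.28). The reads of the member Mir299b lay on the strand opposite to it, where the annotation places Mir299a.

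Epithelial and sensory microRNAs were higher in pup 3. Of 7 epithelial members, 6 were called higher and 1 was not called, with a median log2 ratio of 1.75 (3.36-fold, percentile 100), and the counts were 6 and 0 when adjusted over the list alone. Mir429 had a log2 ratio of 1.48 (1.455 to 1.503), Mir200b of 2.09 (2.05 to 2.13), Mir200a of 2.18 (2.09 to 2.26) and Mir141 of 1.99 (1.87 to 2.12). The keratinocyte microRNA Mir203, in the same list, passed at 0.07 but had -0.13 under total counts, where 5 members were higher and 1 lower. Mir205 had 0.24 and did not pass. All 3 sensory members were called higher, also adjusted over the list alone, with a median of 1.98 (3.95-fold, percentile 99.6). Mir182 had 2.23 (2.17 to 2.29), Mir96 had 1.98 (1.89 to 2.08) and Mir183 had 1.13 (1.06 to 1.20). The 3 sensory members lie in a single genomic cluster. Most epithelial members lie in the clusters of Mir200b with Mir429 and of Mir200c with Mir141. Neighbouring hairpins need not vary independently, and the random lists ignored position, so both percentiles describe the lists in these libraries only.

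The proliferation-linked miR-17-92 list was also higher in pup 3, by less. Of 13 members, 9 were called higher, 2 lower and 2 not, and 10 were higher and 2 lower adjusted over the list alone. The median log2 ratio was 0.49 (1.40-fold, percentile 98.7), and among members with a mean of 100 CPM or more it was 0.44 at percentile 96.7, inside the range of random lists. Under total counts 7 were higher and 2 lower, with a median of 0.29. Mir17 had a log2 ratio of 1.12 (1.11 to 1.13), and Mir93 of the paralogous cluster had 0.96 (0.94 to 0.97). The members of this list also lie in a few clusters, so its percentile describes these libraries only.

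**Figure D3:**
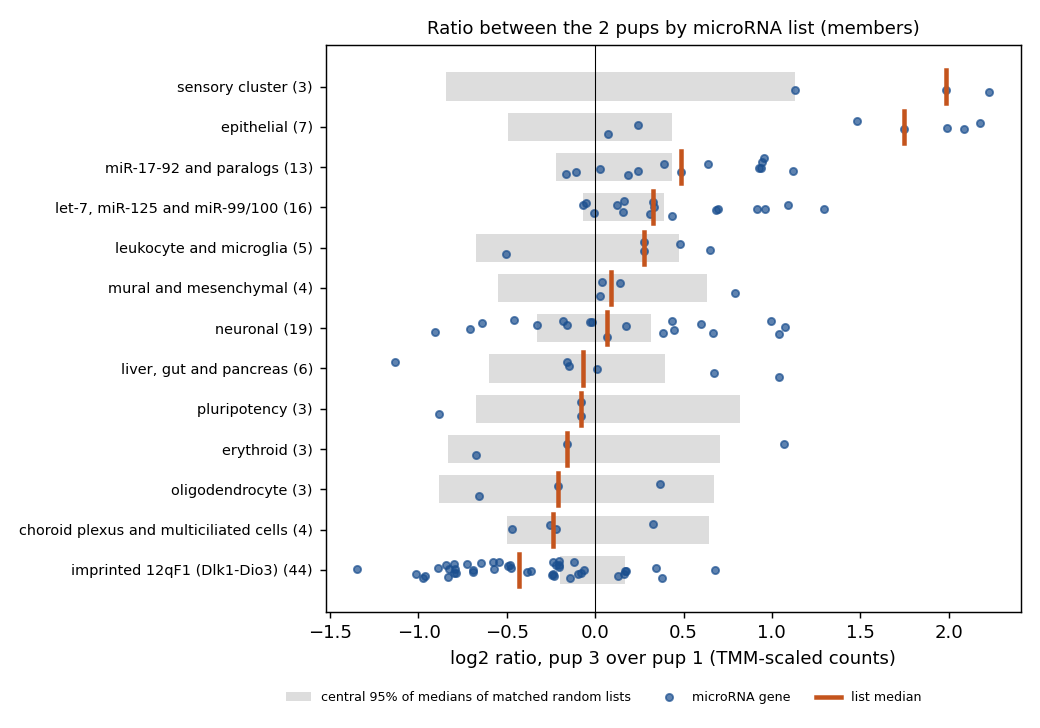
Log2 ratio of pup 3 over pup 1 (TMM-scaled counts, horizontal axis) of the members of 13 microRNA lists, with points for genes, thick bars for list medians and grey bands for the central 95% of medians of matched random lists. The medians of the sensory list at 1.98, the epithelial list at 1.75, the miR-17-92 list at 0.49 and the 12qF1 list at -0.43 lie outside their bands, and the other 9 lie inside.

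The remaining 9 lists lay within the range of matched random lists. Of 16 let-7, miR-125 and miR-99/100 members, 13 were called higher, 2 lower and 1 not, with a median log2 ratio of 0.33 at percentile 93.9, and the counts were the same adjusted over the list alone. Under total counts 10 were higher and 6 lower, with a median of 0.13. Over the 9 members without a shared stretch the median was 0.16 at percentile 51.9. Of 19 neuronal members, 8 were called higher, 6 lower and 5 not, and 8 were higher and 7 lower adjusted over the list alone. The neuronal median was 0.07 under TMM scaling and -0.13 under total counts, where 8 were higher and 9 lower. Of 5 leukocyte and microglial members, 4 were higher and 1 lower, with a median of 0.28, and 2 were higher and 1 lower under total counts. Of these, Mir142b had reads on the strand opposite to it, where the annotation places Mir142, a microRNA of blood cells. Of 4 mural and mesenchymal members, 2 were called higher and 2 were not, with a median of 0.09 that was -0.11 under total counts, where 1 was higher and 2 were lower. Of 4 choroid plexus and multiciliated members, 1 was higher and 3 were lower, with a median of -0.24. Of 3 oligodendrocyte members, 1 was higher and 2 were lower, with a median of -0.21. Of 3 erythroid members, Mir451a was higher (log2 ratio 1.07), Mir144 was lower (-0.67) and 1 was not called, with a median of -0.16. Of 6 members of the liver, gut and pancreas list, 2 were higher, 2 lower and 2 not called, with a median of -0.07. Of 3 pluripotency members, 1 was lower and 2 were not called, with a median of -0.08, and all 3 were lower under total counts. Adjusted over the list alone, 3 rather than 2 members of the liver, gut and pancreas list were lower, and the other 6 of these 7 small lists had the same counts.

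Among single genes, the lowest ratios beside Mir496a belonged to genes of several chromosomes. Gm25750 had a log2 ratio of -1.40 (-1.45 to -1.35), and its reads lay on the opposite strand, where the annotation places the imprinted hairpin Mir380. Mir700 in an exon of Rcan3 had -1.31, Mir3099 in an intron of Usp29 had -1.27 and Mir760 had -1.27. Of the 20 most abundant genes, Mir17 (1.12), Mir15a (1.09) and Mir30e (1.07) were at least 1.5-fold higher in pup 3. Mir135b (0.73), Mirlet7i (0.69) and Mir137 (0.66) were so under TMM scaling but not under total counts (0.53, 0.49 and 0.46). Mir100 had -0.01 (adjusted p = 0.316, exact binomial test), and Mir22 had 0.00 (adjusted p = 0.664, exact binomial test); neither passed under TMM scaling.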

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

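All tests in this part were chosen before the result they measure was seen, although the low counts of Mir124a-3 were known when its explanation was written down.

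Reads outside the gene counts made up more of each library than the reads inside them. In pup 1, 43.0496% of reads (9673667) mapped to several places and 1.84838% (415349) lay in no microRNA gene. In pup 3 these were 43.4679% (8171236) and 1.25807% (236496). These reads drew attention because the tables give only their number, above the limit that a count of 0 allows, and no comparison of genes uses them.

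Some multi-copy hairpins, such as those of Mir124a, stood near the floor in both pups, while others, such as Mir487b and Mir181a-1, were abundant. If reads shared between copies lower such counts, hairpins with a shared stretch should fall below the unshared partners of their own genomic cluster. This held in 13 of 15 clusters (exact two-sided sign test p = 0.00739, median log2 difference in CPM -4.63). The exceptions were the cluster of Mir15b and Mir16-2 and the second 12qF1 cluster, where Mir487b and Mir411 were among the shared members. The Mir124a hairpins lie in none of these clusters, so the test does not cover their own low counts. Some clusters hold hairpins that share a stretch with each other, such as Mirlet7a-1 and Mirlet7c-2, so the clusters are not all independent. Differences in processing or stability between hairpins of a cluster were not tested and stay open. No biological explanation was tested, since the design holds 1 group.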

How the results depend on the processing

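Members without shared stretches and removal of the GC trend were chosen as settings only after the data were seen; the others were planned. The medians of the 12qF1, epithelial and sensory lists kept their direction and their place outside the range of random lists at a mean of 100 CPM or more and with the GC trend removed, as did 12qF1 over unshared members. That CPM filter removed no sensory members. Over all settings the 12qF1 median ran from -0.63 to -0.42; under total counts 1 epithelial member, Mir203, was lower (-0.13). The miR-17-92 list fell inside that range at a mean of 100 CPM or more (0.44, fewer members tested). Other scalings move all log2 ratios by the same amount and so cannot move a list against random lists, and the epithelial and sensory lists have no shared members to leave out. Under total counts the neuronal (-0.13) and mural (-0.11) medians reversed, as did Mir99a (-0.078), Mirlet7g (-0.042), Mir126a (-0.14), Mir149 (-0.15), Mir26b (-0.092), Mir181c (-0.0045) and Mir22 (-0.20). Mir100 reversed with DESeq2 factors (0.0060). Over unshared members the neuronal median was -0.093, the let-7 list's 0.16, and 9 lists were in the top 2.5% of random lists by CPM, and the cause was not tested. The biological coefficient of variation was 0.314 with total counts, 0.308 with no filter, 0.313 at 100 CPM or more and 0.255 on the opposite strand, and the cause was not tested. With 1 count as the minimum, 665 genes were detected. The sense strand gave a share of 54.3% for the 10 most abundant genes. The opposite strand holds few genes and gave 14 detected genes, a share of 99.3%, 3 lists in the top 2.5% of random lists and 11 called genes. Random lists of detected genes left 3 lists there, since that background has no genes at 0. With either pup alone, the detected genes were 444 to 473, the share of the 10 most abundant 52.6% to 53.5%, and 12 lists were in the top 2.5%. A spread or a ratio needs both pups, so no pup could be left out of those. No paired analysis was possible because there is 1 group. What depth limits was not tested by downsampling.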

Other observations

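The tests on the miR-200 and miR-183 set, on clusters without that set, and on shared against unshared hairpins were chosen only after the result was seen, as was the search for genes read from the opposite strand. The need for a distance above the SD of the members, in the test of fewer neurons, was also added after the values were seen.

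Several known forebrain microRNAs were counted under the name of a gene on the other strand. In 11 genes with at least 100 reads in each pup, 90% or more of the reads lay opposite to the named gene, and all 11 overlap an annotated hairpin on that strand that has no entry of its own in the tables. These genes held 99.8% and 99.7% of the opposite-strand reads of pups 1 and 3. Reads at Gm25927 lay on the strand of Mirlet7e, a let-7 hairpin next to Mir99b, at 5467 ± 1043 CPM. Reads at Gm25252 lay on the strand of Mir376a (6089 ± 2149 CPM) and reads at Gm24321 on that of Mir409 (3051 ± 820 CPM), both in the imprinted 12qF1 region. Reads at Gm24083 lay on the strand of Mir191 (2964 ± 0.965 CPM), and reads at Gm25301 on that of Mir378a, in an intron of the metabolic gene Ppargc1b (2004 ± 551 CPM; SD, n = 2). The last of these shares a stretch with Mir378c, so its count is uncertain.

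Imprinted 12qF1 hairpins had a median log2 ratio of -0.43 between pups. A linear bias on the GC content of the hairpin is argued against, since the median was -0.43 with a linear GC trend removed, outside the random range of -0.22 to 0.14. The list's median GC of 47.8% against 50% in other genes also lies on the side that this trend raises in pup 3. Bias on the GC content of the mature microRNA was not tested. For fewer neurons in the pup 3 forebrain, the neuronal median was 0.065, at percentile 67.3 and above the 12qF1 upper quartile of -0.14. That met the prediction written beforehand against this cause. The condition added later was not met, as the distance of 0.50 from the 12qF1 median was smaller than the SD of 0.60 over neuronal members. Those members went both ways, and over the 8 without a shared stretch the median was -0.093 at percentile 36.6. Fewer neurons may therefore still contribute. A difference between animals or dissections stays open and untested. No other biological explanation was tested, since the design holds 1 group.

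The miR-200 family and the miR-183 cluster, 8 genes, were higher in pup 3, from 0.450% of assigned reads in pup 1 to 1.30%, with a median fold of 3.97. The set's median hairpin GC of 50.5% was close to the 50% of other genes, so a linear GC trend had little to remove. The median log2 ratio was 1.96 with that trend removed and 1.99 before, so a linear trend does not account for it. Other forms of hairpin GC bias were not tested. The set was chosen after its ratios were seen, so its place outside the random range of -0.49 to 0.53 is no separate evidence. Bias on the GC content of the mature microRNA was not tested. For skin, pituitary or gut epithelium in the dissection, Mir203, Mir205 and Mir375 had a median log2 ratio of 0.072. Their upper 95% limits of 0.11, 0.59 and -0.07 lay below the 1.13 of the lowest gene in the set. This argues against these tissues as the whole cause only if the markers had no other source, which was not tested. Mir203 stood at 1642 CPM in pup 1, above Mir200b at 820 CPM, so a source present in both pups could mask a rise. Olfactory tissue and differences between animals have no separate marker in the lists, so they stay open and untested, and no biological explanation was tested.

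Hairpins of a genomic cluster are often cut from 1 transcript, so the hypothesis was tested that they share their ratio between pups. Over 25 clusters and 62 genes, with the 12qF1 clusters left out, the mean within-cluster variance of the log2 ratio was 0.357 against a permutation median of 0.556 (one-sided permutation p = 0.0186 across genes). Without the 3 clusters of the miR-200 and miR-183 set, it was 0.382 against 0.313 over 22 clusters (one-sided permutation p = 0.8673), so the result rested on those clusters. In the other clusters the variance lay above the permutation median, in the direction opposite to sharing, and gave no evidence of a shared ratio. Some of these clusters pair a hairpin with a shared stretch, whose count is uncertain, with one without. Mir15b with Mir16-2 and Mirlet7b with Mirlet7c-2 had SDs of the log2 ratio of 1.07 and 0.954. Mir98 with Mirlet7f-2 had 0.247, and Mir144 with Mir451a, neither shared, had 1.23. Uneven counting can therefore not be told apart from unlike ratios here. A separate comparison found no difference past the threshold in the log2 ratio of 72 shared and 238 unshared hairpins (median difference 0.14, two-sided permutation p = 0.1215 across genes).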
